A study of Homo sapiens with 2 samples.

How the data were processed

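Gene expression was measured in SW480 cells, an established human colorectal adenocarcinoma line, on 2 Affymetrix arrays hybridised with biotin-labelled target from total RNA. Per the labels' protocols, the cells were stable transfectants kept under Geneticin selection for some weeks, single clones were picked and tested for TFAP2E expression, and RNA was prepared with a silica column kit. The labels put 1 array in each group, TFAP2E overexpression and empty vector control. They do not say whether an array holds RNA of 1 clone or of several. The pTarget plasmid named in the series' design text is a mammalian expression vector, and the control cells carried it without the TFAP2E sequence.

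The deposited values are log2 expression values per probe set, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, sets the arrays to a common distribution of probe intensities and summarises the probes of each probe set on the log2 scale. Its version, the software used and the genome build are not given in the sources used here, and therefore no coordinates are printed. The deposited table held 33297 probe sets, with log2 values from 1.42 to 13.1 and a median of 5.54 on the TFAP2E array, and from 1.34 to 13.3 with a median of 5.56 on the control array. After sorting, the arrays differed by at most 0.158 at any rank, as is usual after quantile normalization. Scanner files were not used here. RMA pulls the arrays to 1 distribution, so that a change of all transcripts in the same direction would not appear in these values.

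Probe sets were named through the platform annotation. Of the 33297 probe sets, 19460 had exactly 1 gene symbol, 1754 had several, and 12083 had none and stayed unnamed here. Symbols were updated through the Entrez identifier in a RefSeq gene table (assembly GRCh38.p14), in which 19429 of the 19460 were found. The 19460 probe sets stood for 18417 genes, of which 769 had several probe sets. For those, the probe set with the highest mean over both arrays was used. A gene entered the comparison when the higher of its 2 values was at or above 5.55, the median of all probe sets over both arrays. This left 11548 genes and set aside 6869 as dim. The deposited values were not scaled further. For genes past the 2-fold rule whose lower value lay below 5.55, called dim on that array, the report also counts the difference from 5.55 to the higher value. This was chosen after the values were seen. The value 5.55 is a median and not a detection limit. In such counts "at least" therefore marks a cautious count and not a bound with a known error.

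With 1 array per group there is no replicate, so no test, p-value or error can be given for any gene. The number of arrays limits the precision. Each gene's difference is the log2 value of the TFAP2E array minus that of the control array, and a difference of at least 2-fold (1 on the log2 scale) served as a fixed rule of size. Across the 11548 genes the differences had a median of 0.04, a standard deviation of 0.219, and 95% of them lay between -0.37 and 0.47. This spread holds the noise of the assay and real differences together. For 43 gene lists, the median difference of the genes measured was placed among the medians of 10000 random lists of equal size, matched on mean expression in 20 bins. A list is said to stand apart when it lay below percentile 2.5 or above percentile 97.5. Lists with fewer than 5 measured genes got no percentile, and TFAP2E was left out of all lists. Such percentiles describe these 2 arrays. Genes of a pathway vary together more than random genes do, so that a list may stand apart more often than 5% of the time with no treatment at all.

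The groups, the gene lists, the rule of size, the filter, most alternatives and the rule for named genes were fixed before the data were examined. The named genes are TFAP2E, DKK4, the 12 genes with the largest positive and the 12 with the largest negative difference, the 2 highest and 2 lowest genes of each list that stood apart and of the AP-2 and Wnt lists, and the members of lists with fewer than 5 measured genes. Other genes are named only where the text says that they were chosen after their values were seen. The alternatives were 3 other scalings (centring on the median, quantile normalization, removal of a loess trend), 3 other filters, the mean of a gene's probe sets, a floor at the 20th percentile, thresholds of 1.5-fold and 3-fold, counting of all probe sets, random lists without matching, and list means. Others were added after the data were seen: matching of random lists on gene length, removal of genes in shifted windows of neighbouring genes, and protein-coding genes alone. The order of genes along chromosomes came from the RefSeq table and was used only to find neighbours.

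The scripts were tested on simulated data with the real expression levels and the real spread per level. Of 50 genes each, simulated with a change of 1.5-fold, 2.5-fold, 4-fold and 8-fold among 11548 genes, the rule of size found 1, 49, 50 and 50, with 0 calls among 11348 unchanged genes. The simulated noise was normal, with a spread set by the bulk of the differences at each level, without the wide tails that real array noise can have. The 0 calls therefore do not measure how often the rule calls unchanged genes on real arrays. Of 120 unshifted lists of 20 genes, 6 lay outside the central 95%, against 33 of 60 lists shifted by 0.1 and 59 of 60 shifted by 0.2. In a test with 160 genes in 2 planted segments shifted by 0.2, the search for neighbouring genes found 122 of them and 25 genes beside them. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.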

Results

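The transcriptome of SW480 cells stably transfected with the coding sequence of TFAP2E was compared with that of SW480 cells carrying the empty vector, on 1 array each. TFAP2E encodes AP-2 epsilon, a member of the AP-2 family of DNA-binding transcription factors. The comparison asks which transcripts differ when TFAP2E is introduced into this colorectal cancer line. The arrays were close to each other, with a Pearson correlation of 0.986 across the 11548 genes that passed the filter on dim genes. Values are log2 RMA values, differences are given as the TFAP2E-labelled array minus the empty vector array, and no value has a replicate.

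The TFAP2E probe set read 6.81 on the TFAP2E-labelled array and 6.77 on the empty vector array, a difference of 0.04. This lies well inside the range of -0.37 to 0.47 that held 95% of genes, and is close to the median difference of all genes, 0.04. The array values therefore do not show the introduced gene. Which part of the transcript the probe set covers is not given in the sources used here, so that the value neither bears out nor contradicts the labels. All directions below rest on those labels.

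DKK4 differed strongly. This secreted Wnt antagonist, which the study's authors have linked to TFAP2E in published work, read 7.96 on the TFAP2E-labelled array and 10.4 on the empty vector array. It was 5.32-fold lower (log2 difference -2.41), the lowest of all 11548 genes. DKK1, another member of the family, named here after its value was seen, differed by -0.05, and DKK3 by 0.16. A second, dim probe set of DKK3 read 0.42 lower on the log2 scale (-0.42). Of the 7 measured genes in the list of secreted Wnt antagonists, which also holds Dickkopf receptors, 5 were lower and 2 higher. DKK4 alone passed the 2-fold rule. Besides DKK4 the lowest member was NOTUM, a Wnt deacylase, at -0.33, and the highest besides DKK3 was the Dickkopf receptor KREMEN1 at 0.12. The list's median of -0.05 lay at percentile 9.64 of random lists, while its mean, which DKK4 dominates, was -0.39, below the mean of each random list.

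At the 2-fold rule, 23 of the 11548 genes differed, 0.199% of them, with 10 higher and 13 lower in the TFAP2E-labelled array. At 1.5-fold the counts were 103 higher and 70 lower. ASB4, an ankyrin repeat and SOCS box protein, was 8.65-fold higher, at 9.21 against 6.10. MAGEC2, a cancer-testis antigen, read 8.0 against 3.42 (log2 difference 4.58). Its value on the empty vector array was dim. MAGEC2 was at least 5.47-fold higher when counted from the filter value of 5.55, and its rank against ASB4 stays open. SYTL3, a synaptotagmin-like protein, was 2.82-fold higher. The glutamate transporter SLC1A2 (log2 difference 1.28) and the microvillus actin-bundling protein VIL1 (villin, 1.28) were dim on the empty vector array, and were at least 2.35-fold and at least 1.59-fold higher by the same count. GMFG was 2.39-fold, the mitochondrial creatine kinase CKMT2 2.36-fold and SPTSSB, a small subunit of serine palmitoyltransferase, 2.03-fold higher. The other 2 genes past the rule were small RNAs, the U5 spliceosomal RNA RNU5D-1 (2.22-fold higher) and the small nucleolar RNA SNORA22 (log2 difference 1.05, dim on the empty vector array, at least 1.99-fold higher). The stress-induced mTORC1 inhibitor DDIT4 (0.98) and the adaptor GRB10 (0.93) completed the highest 12 without reaching 2-fold.

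**Figure D1:**
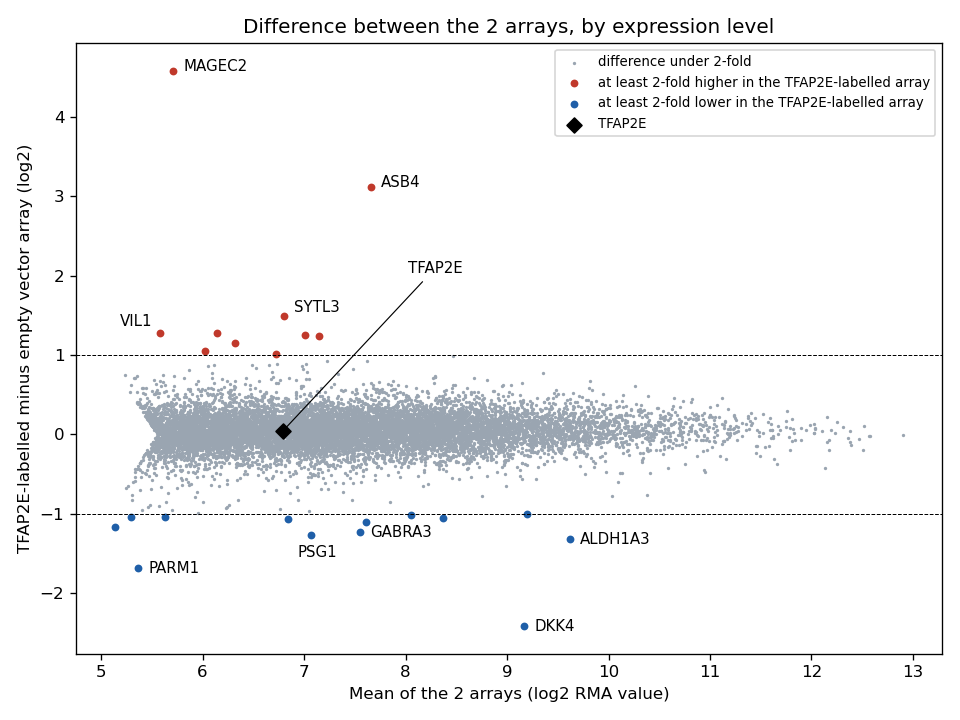
Difference between the arrays (TFAP2E-labelled minus empty vector, log2, y axis) against the mean of both arrays (log2 RMA value, x axis) for the 11548 genes, 1 point per gene, with dashed lines at 2-fold. MAGEC2 and ASB4 stand above and DKK4 below the other genes, and TFAP2E (diamond) lies at 0.04.

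Among the other lower genes, ALDH1A3, which makes retinoic acid, was 2.48-fold lower at a high level of expression, at 8.96 against 10.3. Its second probe set differed by -0.61, and the mean over both was -0.96. PSG1, a pregnancy-specific glycoprotein with near-identical relatives that can share probes, was 2.40-fold lower. The GABA receptor subunit GABRA3 was 2.34-fold, the adhesion scaffold NEDD9 2.14-fold and the growth factor FGF9 2.09-fold lower. GPR155 was 2.07-fold lower, and TNFRSF11B (osteoprotegerin, a decoy receptor) was 2.01-fold lower. Another 4 were dim on the TFAP2E-labelled array. PARM1, a mucin-like membrane protein, read 4.53 against 6.20 (log2 difference -1.68) and was at least 1.58-fold lower when counted from the filter value, and the chondroitin sulfate enzyme CSGALNACT1 differed by -1.17 and was at least 1.13-fold lower. RNPC3 and the pseudogene DUSP5P1 differed by -1.04 each and were at least 1.20-fold and 1.52-fold lower. Their second probe sets were dim on both arrays and do not bear on this. Only the 12 lowest genes are named, so that not all of the 13 lower genes past the rule appear here. In all, 8 of the 23 genes were dim on 1 array, and 2 of those 8 stayed past 2-fold when counted from the filter value.

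Of the 37 gene lists with at least 5 measured genes, 14 stood apart from random lists, where 1.85 would for independent random lists. In the TFAP2E-labelled array 11 of them lay lower and 3 higher. The shifts were small, and no member of these 14 lists passed the 2-fold rule. Small RNAs were looked at only because RNU5D-1 and SNORA22 were among the highest 12 genes, and both are counted here. Of 9 small nuclear RNAs 8 were higher in the TFAP2E-labelled array (median 0.45), as were 48 of 77 small nucleolar RNAs (median 0.12). Several of the small nuclear RNAs are close copies of each other and are not independent.

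Wnt/beta-catenin target genes stood lowest. Of 17 measured members 14 were lower and 3 higher, with a median of -0.23, below each of the 10000 random lists. The stem cell factor ASCL2 differed by -0.54 and BMP4 by -0.53, while the highest members were MYC at 0.24 and CDX1, an intestinal homeobox factor, at 0.06. AXIN2 (-0.40), RNF43 (-0.37) and NKD1 (-0.28), feedback inhibitors of the pathway that were picked after their values were seen, were also lower. None of the 17 reached 1.5-fold. Among the 28 measured Wnt ligands and receptors, 13 were higher and 15 lower, and the list did not stand apart (median -0.02, percentile 8.56). WNT11 had the highest difference there, at 0.54, and FZD7 the lowest, at -0.45, with WNT5A at -0.36 and FZD2 at 0.29. The 9 measured intestinal stem cell markers had a median of -0.01 at percentile 22.3.

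Genes of the cell cycle were lower as groups. In the replication list 21 of 30 genes were lower, with a median of -0.13, again below each random list. The methylation maintenance factor UHRF1 differed by -0.39 and the replisome subunit GINS2 by -0.37, against 0.32 for the clamp loader subunit RFC4 and 0.31 for POLE2. In the mitosis list 20 of 29 genes were lower (median -0.05, percentile 0.16), from the proliferation marker MKI67 at -0.50 and the kinase AURKB at -0.24 to NUF2 at 0.22 and BUB1 at 0.16. Of 25 replication-dependent histone genes 15 were lower and 9 higher (median -0.08, percentile 0.33). H1-2 differed by -0.36 and H4C2 by -0.35, H4C3 by 0.19 and H4C9 by 0.13. Histone genes are near-identical copies, so that their probes cannot fully tell them apart. The p53 target genes, including the cell cycle inhibitor CDKN1A at 0.11, did not stand apart (median 0.09, percentile 82.8).

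Unfolded protein response and amino acid stress genes, oxidative phosphorylation genes and metallothioneins were higher as groups. In the list of unfolded protein response and amino acid stress genes, 26 of 28 members were higher (median 0.21, percentile 99.98). DDIT4 at 0.98 and the transcription factor DDIT3 (CHOP) at 0.82 led it, and SLC3A2 at -0.10 and CRELD2 at -0.06 were lowest. Further members, picked after their values were seen, were asparagine synthetase ASNS (0.68), the cystine transporter SLC7A11 (0.56), the unfolded protein sensor ERN1 (0.45) and HERPUD1 (0.36) on the high side, and the endoplasmic reticulum chaperones HSPA5 (0.02) and HSP90B1 (0.02) and the serine enzyme SHMT2 (0.05) near 0. In the oxidative phosphorylation list 23 of 26 genes were higher (median 0.20, percentile 99.98), led by COX6C of complex IV at 0.56 and SDHD of complex II at 0.40, with NDUFB3 (-0.10) and SDHA (-0.05) lowest. Of 7 metallothioneins, the metal-binding proteins, 6 were higher (median 0.34, percentile 99.92), from MT1H at 0.51 and MT1F at 0.47 to MT2A at 0.29 and MT3 at -0.02. These genes are close paralogs and are not independent. Ribosomal proteins (median 0.11, percentile 91.3) and heat shock genes (median 0.07, percentile 64.8) lay inside the range of random lists.

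**Figure D2:**
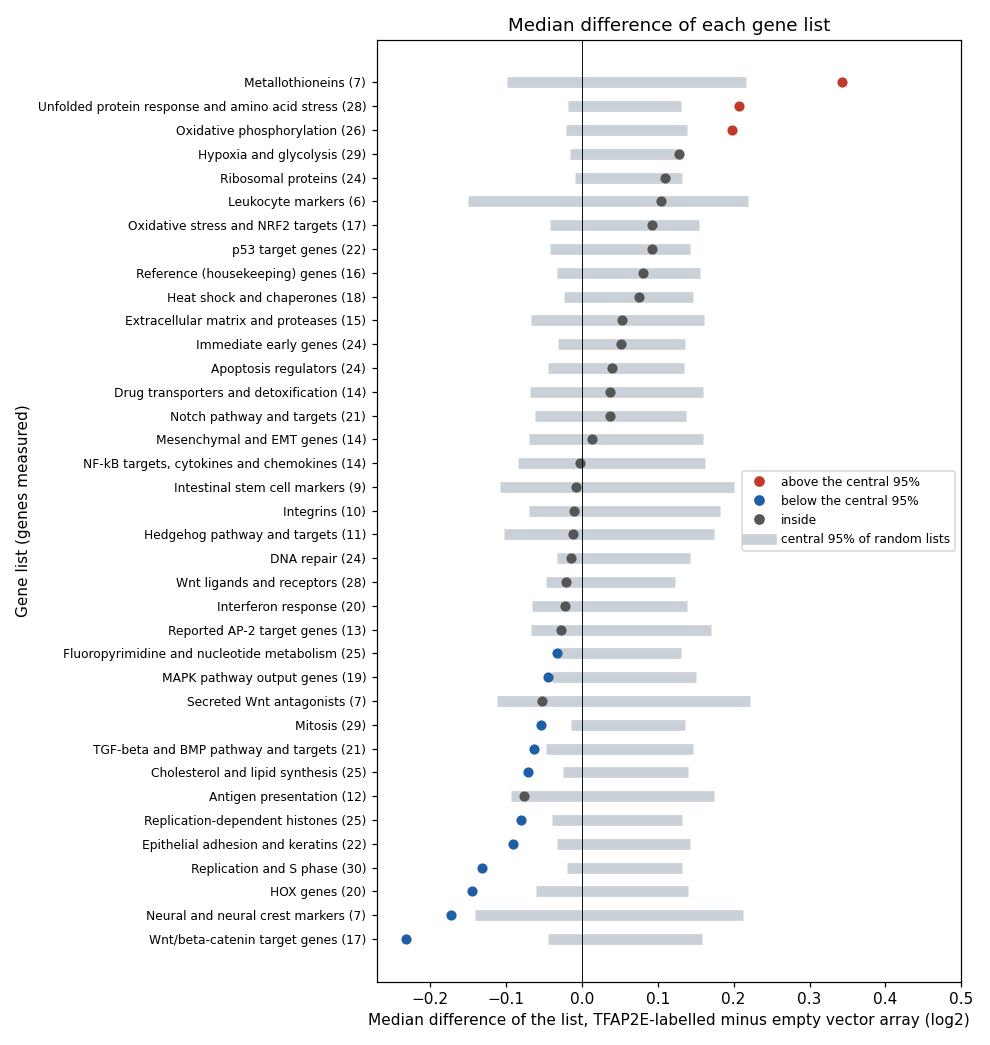
Median difference (TFAP2E-labelled minus empty vector array, log2, x axis) of the 37 gene lists (y axis, genes measured in brackets), as points, over the central 95% of 10000 random lists matched on expression, as grey bars. Wnt/beta-catenin targets lie lowest at -0.23 and metallothioneins highest at 0.34.

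Epithelial adhesion and keratin genes were lower in 16 of 22 cases (median -0.09, percentile 0.15). CDH1, which encodes E-cadherin, was 1.63-fold lower (-0.71) and the membrane protease ST14 differed by -0.44, while the desmosomal cadherin DSG2 (0.34) and CLDN1 (0.22) were highest. Mesenchymal genes did not stand apart (7 of 14 lower, median 0.01, percentile 30.03). The mean of that list was -0.09, opposite in sign to its median, and lay at percentile 0.99. HOX genes were lower in 13 of 20 cases (median -0.14, percentile 0.02). HOXB8 (-0.65) and HOXB2 (-0.60) were lowest, and HOXD10 (0.43) and HOXB13 (0.14) highest. The cholesterol and lipid synthesis list had 19 of 25 genes lower (median -0.07, percentile 0.15), with ELOVL6 at -0.38 and DHCR7 at -0.33, against 0.32 for SQLE and 0.17 for MSMO1.

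TGF-beta and BMP genes split evenly by sign, 11 lower and 10 higher, with a median of -0.06 at percentile 1.08. TGFB2 (-0.63) and BMP4 were lowest, at -0.53 for BMP4, and LTBP2 (0.30) and BMP2 (0.26) highest. Of 19 genes induced by MAPK signalling 10 were lower (median -0.04, percentile 1.97), from the feedback inhibitor SPRY4 (-0.56) and EPHA4 (-0.28) to the EGF receptor ligand HBEGF (0.61) and ETV1 (0.20). Of 25 genes of fluoropyrimidine and nucleotide metabolism, chosen because fluorouracil is a main drug in this cancer, 14 were lower and 11 higher (median -0.03, percentile 2.27). Uridine phosphorylase UPP1 was 1.83-fold higher (0.87) and MTHFD2 differed by 0.33, whereas GGH (-0.48) and SHMT1 (-0.41) were lowest. The MAPK and fluoropyrimidine lists each stopped standing apart under 4 of 12 alternatives, among them removal of the loess trend, at percentiles 5.77 and 2.51.

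**Figure D3:**
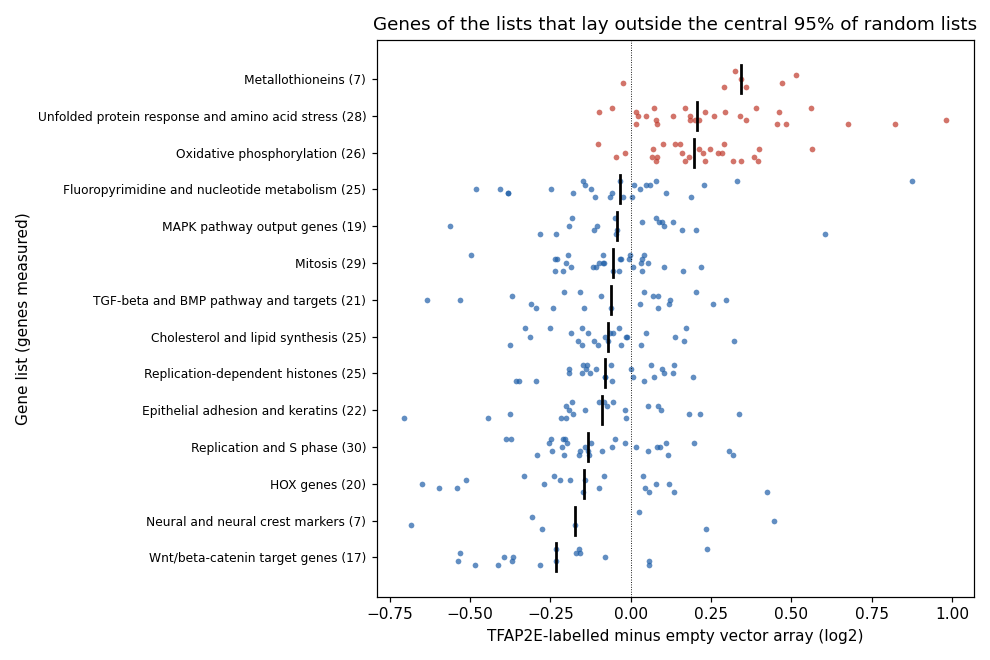
Differences (TFAP2E-labelled minus empty vector array, log2, x axis) of the single genes, as points, in the 14 lists that stood apart (y axis, genes measured in brackets), with the list median as a black bar. Nearly all genes of the stress and oxidative phosphorylation lists lie above 0, while the TGF-beta and MAPK lists spread to both sides.

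Reported AP-2 target genes did not stand apart by their median, and the AP-2 family had too few measured members for a percentile. TFAP2C, the only other family member above the filter, differed by -0.54, and TFAP2A, TFAP2B and TFAP2D were dim. Of 13 measured genes reported as AP-2 targets 8 were lower and 5 higher (median -0.03, percentile 7.93; mean -0.07, percentile 1.62), with CDH1 at -0.71 and the keratin KRT5 at -0.43 lowest, and EGFR at 0.52 and CDKN1A at 0.11 highest.

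Markers of differentiated intestinal cells were mostly dim. Of 24 absorptive enterocyte markers on the array 4 were measured, VIL1 at 1.28, ALPI at 0.25, APOA1 at 0.04 and GUCA2B at -0.13. Of 27 secretory markers 3 were, TFF2 at 0.21, INSM1 at 0 and TFF1 at -0.06. Among cancer-testis antigens only MAGEC2 and CTAG2 (0.10) of 18 passed the filter. Markers of other cell types were likewise dim, 14 of 17 for fibroblasts (ACTA2 0.33, COL1A1 0.05, COL1A2 -0.09), 11 of 14 for endothelium (ENG 0.00, EGFL7 -0.09, CLDN5 -0.13) and 14 of 20 for leukocytes. The 6 measured leukocyte markers had a median of 0.10 at percentile 78.4. Neural markers stood apart on 7 measured genes (median -0.17, percentile 1.24), with the adhesion molecule NCAM1 at -0.68, NES at -0.31, NEFL at 0.45 and ENO2 at 0.23. That list lay at percentile 21.03 when dim genes were included and at 5.79 by its mean.

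The 16 measured reference genes had a median of 0.08 at percentile 66.9. The remaining lists, immediate early genes (median 0.05), interferon response (-0.02), antigen presentation (-0.08), NF-kB targets and cytokines (0.00), Notch (0.04) and Hedgehog (-0.01) genes, integrins (-0.01), extracellular matrix (0.05), apoptosis regulators (0.04), DNA repair (-0.01), drug transporters and detoxification (0.04), NRF2 targets (0.09) and hypoxia and glycolysis (0.13), lay inside the central 95% of random lists. Hypoxia and glycolysis lay near its edge, at percentile 96.89, and moved outside, higher, under 3 of 12 alternatives, and antigen presentation (percentile 4.58) moved outside, lower, under 2. Median and mean differed in sign for the drug transporter list (mean -0.08, at percentile 1.30) and for the interferon (mean 0.05), Notch (mean -0.02) and DNA repair (mean 0.02) lists, whose means also lay inside the range of random lists.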

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

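The count of genes at 2-fold depended on the threshold and on which probe sets entered. Of the 10 higher and 13 lower genes, 5 and 8 passed a filter at the 75th percentile of all probe sets. A 1.5-fold threshold gave 103 and 70, and a 3-fold threshold 2 and 2. Counting all probe sets above the filter, named or not, gave 21 and 75. The changes with the 75th percentile filter and the other thresholds follow from how the settings are built. The count of all probe sets also takes in unnamed ones. Above the filter 1.82% of those passed 2-fold, against 0.189% of the named ones. The other alternatives for these counts gave 7 to 12 higher and 10 to 15 lower genes. The median of all genes, 0.04, became 0.07 with centring, 0.02 with quantile normalization and 0.01 without the loess trend. Counts of higher and lower genes in a list are taken from 0, so that genes near 0 can change sign with the scaling. TFAP2E stayed between 0.01 and 0.06 in each scaling. The number of lists that stood apart, 14, was 12 to 16 in all 12 alternatives, and between 12 and 14 of the 14 lists kept their side in each. The MAPK list ended inside the central 95% under 4 of the 12 (percentile 6.34 with quantile normalization, 5.77 without the loess trend, 3.75 without matching, 6.22 by its mean), and the neural list under 2 of the 11 that left it at least 5 genes (21.03 with no filter, 5.79 by its mean). The fluoropyrimidine list ended inside the central 95% under 4 of the 12. With no filter on dim genes its median turned to 0.0055. There 4 more of its genes entered, all of them higher, at 0.05 to 0.36, which raised the median. Why the list moved under the other alternatives was not tested. These 10 were all the moves inward, and 418 of the 440 list values kept their side. The other 12 moved out, 3 of them for hypoxia and glycolysis (percentile 97.82 with no filter, 98.76 with the 75th percentile filter, 98.45 without the shifted segments), 2 for antigen presentation (2.09 with quantile normalization, 1.15 with the 75th percentile filter), 2 for the secreted Wnt antagonists, and 1 each for the interferon, Notch, AP-2 target, drug transporter and mesenchymal lists. Of 510 values of named genes 506 moved by less than the standard deviation of all genes, 0.219. The other 4 were genes with a second probe set, dim except for ALDH1A3, averaged to -0.96 for ALDH1A3, -0.56 for DUSP5P1, -0.51 for RNPC3 and -0.13 for DKK3. No paired analysis was possible because each group has 1 array. No replicate could be left out for the same reason. Signal near background limits the comparison, since 6869 of 18417 genes were dim on both arrays.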

Other observations

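The tests below on neighbouring genes against shuffled orders, on whole chromosomes, on TFAP2E, on gene classes and on gene length were chosen after the data were seen, while what the held-out, brightness and list tests would show was written before their results were seen.

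Pregnancy-specific glycoproteins, placental members of the carcinoembryonic antigen family, were lower together. All 5 measured members were lower in the TFAP2E-labelled array (median -0.74), with PSG1 at -1.27, PSG11 at -0.89, PSG9 at -0.74, PSG4 at -0.55 and PSG6 at -0.18. The family lies in 1 gene cluster and its members are close in sequence, so that these are not 5 separate observations. The cluster may share genes with the lower segment from GSK3A to ZNF180 described below. The lower glycoproteins and that segment are therefore not taken as separate observations. In the HOX list the lower genes also lay mostly in 1 cluster. Of 9 measured HOXB genes 8 were lower (median -0.27), HOXB13 being the exception, while of 11 other HOX genes 5 were lower and 6 higher (median 0.04).

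In some stretches of chromosomes, neighbouring genes differed in the same direction between the arrays. Windows of 30 neighbouring genes reached a median shift of 0.298 from the median of all genes. Over 1000 shuffled orders the 95th percentile was 0.183 and the maximum 0.216, which argues against chance order. Windows beyond that percentile merged into 11 segments, 6 higher and 5 lower in the TFAP2E-labelled array. The segments held 707 of the 11536 genes placed in order, 6.13%. The longest ran from RNF216 to BAZ1B (166 genes, 137 of them higher, median 0.19) and from POLR2J to RAB19 (101 genes, 0.20). Next were SHQ1 to UROC1 (95 genes, 0.19) and ARMC1 to ZNF706 (79 genes, 0.17), with B9D1 to CRLF3 as the longest lower one (58 genes, -0.18). RNF216 to BAZ1B, SLC25A40 to COPS6 and POLR2J to RAB19 lie on 1 chromosome. There 71.4% of its 535 genes were higher than the median of all genes (median shift 0.14). SHQ1 to UROC1 and MBNL1 to GPR160 lie on another, with 66.6% of 622 genes higher (0.09). Segments on 1 chromosome are therefore not taken as separate observations. A search on every other gene found 6 segments, 5 higher and 1 lower (TOM1L2 to UTP6), in which 75.2% of the 387 genes left out of the search shifted in the segment's direction, from 18 of 30 for IL17RC to CMTM7 to 49 of 60 for MUC12 to MRPS33, and 81.4% of the 215 brighter ones did, which argues against dim genes as the source of these 6. Of these 6, IL17RC to CMTM7 overlapped none of the 11 segments and carried over least, with a held-out median shift of 0.09. A candidate explanation for the others is a difference in DNA copy number between the transfected cells. Regional gene activity without a copy number change and any effect of TFAP2E were not tested and stay open. The search on every other gene did not find POMT1 to ADAMTSL2 and ENTPD2 to TUBBP5, which lie on 1 chromosome. There 285 of the 423 genes outside them were also lower than the median of all genes (median shift -0.07). It also did not find MBNL1 to GPR160, on a chromosome on which 310 of 495 genes outside the 11 segments were higher (0.06). These 495 still hold the stretch from IL17RC to CMTM7. For GSK3A to ZNF180 and HPGD to DUX4, not found either, the rest of the chromosome was near 0 (-0.01 and -0.02).

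TFAP2E itself differed by 0.0398 between arrays on which DKK4 differed by -2.41. Exchanged labels alone, with a probe set that reads the introduced coding sequence, would make TFAP2E lower and do not account for a value near 0. If the probe set does not read it, this value could arise with the labels right or exchanged. If the probe set does read it, the value could arise when the TFAP2E transcript did not differ between the cells of the 2 arrays. No probe positions are given in the values used here, so that these cannot be told apart.

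The 14 lists that stood apart point to a broad, shallow difference, with the Wnt target and replication lists lower and the list of unfolded protein response and amino acid stress genes and the oxidative phosphorylation list higher. Without the genes of the shifted segments all 14 stayed outside on the same side, and with random lists matched on gene length 14 did. After removal of the loess trend 12 did. The segment genes, gene length and the trend are therefore each unlikely to be the whole source. The removal took out only 707 of 11536 genes. Genes outside the segments were shifted too on some chromosomes, with medians of -0.07, 0.06 and 0.05, though near 0 on others. Weaker shifts of neighbouring genes are therefore not excluded as a source. With 1 array per group, an effect of TFAP2E, a difference between clones and a difference in culture density or nutrients at harvest stay open and untested, as does RNA preparation.

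Of the 12083 unnamed probe sets 301 differed by at least 2-fold, 72 higher and 229 lower, against 32 of 21214 named ones. Among probe sets above the filter the shares were 1.82% and 0.189%. Without the filter, the unnamed probe sets past 2-fold had a median level of 3.96, against 6.51 for the named ones. The median level of those above the filter was not taken. What the unnamed ones measure was not looked at, so that their share is not a share of transcripts.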
